A study of Homo sapiens with 8 samples.

How the data were processed

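MCF-7, an estrogen receptor-positive human breast cancer cell line, was grown in medium with charcoal-stripped serum and kept for 24 h with 2 mM succinate or without it, per the labels. Chromatin was precipitated with an antibody against H3K9me3, the trimethylated lysine of histone H3 that marks heterochromatin. There were 3 control and 3 succinate libraries. The 2 input libraries, 1 per treatment, came with no file and were not analysed here. An IgG precipitation is mentioned in the labels as a control of the protocol and was not analysed here.

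The deposited data were 6 lists of broad peaks, 1 per library, with 9 columns each and positions on GRCh38, per the submitters' processing notes. The notes name FastQC, Trim Galore, BWA, Picard, SAMtools, bedtools, deepTools, MACS3, HOMER, featureCounts, DESeq2 and MultiQC without versions, settings or order. Peaks were called by the authors in each library separately, since the 6 lists differ in position and number. The notes do not say whether the inputs were used as background. Because each treatment had its own input, an effect of the input on the peaks cannot be told apart from the treatment. Each peak carried a score, a fold enrichment as a ratio and −log10 values of p and q, as deposited by the authors. The deposited score equalled the whole part of 10 times −log10 q, apart from rounding in a few peaks. All deposited q-values were at most 0.1. These values come from the authors' peak caller and depend on each library's reads, so they served only to rank or select peaks within a list. The lists hold no read counts. The depth of the libraries is therefore unknown, and no counting interval or limit of detection can be given.

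Peaks on chromosomes 1 to 22 and X were analysed. Of the 628565 peaks in the 6 lists, 6513 lay elsewhere and were left out. The percent of a region covered by peaks was computed per library for 303013 windows of 10 kb, and for the bodies of 19974 protein-coding genes from the RefSeq table of the same assembly. Windows with a mean coverage of at least 10% and genes with at least 5% were tested, which left 32710 windows and 2071 genes. Both were fitted with limma 3.58.1 in R 4.3.3, using moderated statistics with a variance trend, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Single values per library were compared with a two-sided exact permutation test, whose smallest possible p with 3 against 3 libraries is 0.1. Differences are succinate minus control, in percentage points of covered length where not stated otherwise. Overlap of libraries was the Jaccard index, the covered length shared by a pair of libraries over that covered by either, with a minimum overlap of 1 bp. Consensus regions of a treatment were bases covered in at least 2 of its 3 libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1 were used, and figures were drawn with matplotlib 3.10.9.

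The mean coverage of 24 gene lists, fixed before the data were examined, was compared per library. The lists were also tested with limma's camera, which sets a list against all other genes, with a preset correlation of 0.01 and again with a correlation estimated from the data, and with fry, which asks whether the members move one way. These list tests used the 7236 genes with any coverage, because genes with none have no variance. This departs from the plan, which had set no filter. The rule for named genes was also fixed beforehand. It takes the 10 genes with the largest rise and the 10 with the largest fall among genes past the threshold whose groups do not overlap. Where fewer pass, the places go to genes whose groups do not overlap, named as not passing. It further takes 2 members of each list with the highest coverage and 2 with the largest difference, and 11 genes of repair, H3K9 methylation, succinate and estrogen signalling. It names 91 genes, of which the text gives those most relevant to each list. For windows it takes 3 in each direction.

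The gene table gives neither strand nor exons. The planned count of promoters was therefore replaced by genes with a peak within 1 kb of either end. Genomic features were reduced to inside or outside protein-coding gene bodies, so exons, introns and untranslated regions were not distinguished. The fits were tested on simulated data made from the real values and their spread. Of 50 genes changed by 5 points, 62% were recovered, and of those changed by 20 points, 94% were. Among 50 windows changed by 40 points, 66% were recovered, and by 20 points, 8%. With the spread of the controls alone these were 74% and 34% for windows, and 66% and 88% for genes changed by 5 and 20 points. The changes of all sizes, 50 features each, were in the same simulated data, which eases the adjusted threshold. Noise was independent between features, with no shift of a whole library. The shares therefore do not give the chance of finding a change in the real data.

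Alternatives planned beforehand were stricter peaks (−log10 q of at least 2 or 5), peaks less than 1 kb apart joined, and each library left out in turn. A further one cut every list to its highest-ranked peaks until it covered 89.0 Mb, the length of the shortest library. For the fits, the replicate number as a block, an arcsine scale, scaling by each library's covered percent, no filter on coverage, no variance trend, windows of 50 kb and genes with 10 kb on each side were also tried. Array weights, scaling together with array weights, and windows of 100 kb were added after seeing the data.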

Results

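H3K9me3 was profiled by chromatin immunoprecipitation and sequencing in MCF-7 breast cancer cells after 24 h with 2 mM succinate, in 3 libraries, and in 3 control libraries. Succinate is an intermediate of the tricarboxylic acid cycle that can inhibit 2-oxoglutarate-dependent dioxygenases, among them the demethylases of H3K9. The series title places the experiment in a study of homologous DNA repair and sensitivity to PARP inhibition. The comparison asked where the heterochromatin mark differed between succinate-treated and control cells. The lists held 99270, 119408 and 114751 peaks in control libraries 1 to 3, and 102814, 84757 and 101052 in succinate libraries 1 to 3. Sequencing depth is unknown, because peak lists hold no counts.

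In both conditions the mark lay over the zinc finger gene clusters. Zinc finger genes, a large family of transcription factors, many of them repressors, were taken as those with a symbol of ZNF and a number. Of these 509 genes, 293 were covered over at least 50% of their body in all 6 libraries. The 19465 other genes include zinc finger genes with other symbols. Of them 88 were so covered, an odds ratio of 299 (Fisher's exact test on genes, which are not independent replicates). ZNF117 on chromosome 7 (64971772 to 64991036, GRCh38) and the protocadherins PCDHB14 and PCDHB15 on chromosome 5 (141223343 to 141227759 and 141245395 to 141249365) were covered over 100% in each of the 6 libraries. ZNF154 on chromosome 19 (57696275 to 57709204) was covered over 100% in controls and 99.1% ± 1.59 with succinate (SD, n = 3). The stretches covered without a break in all 6 libraries were longest at ZNF721 on chromosome 4 (412092 to 473004), near POTEA on chromosome 8 (43755862 to 43812754) and at PCDHB15 on chromosome 5 (141230274 to 141286088). These 3 were picked after their values were seen. At the other end, 12738 of 19974 genes had no covered base in any library.

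Peaks covered less of the genome with succinate on average, and a single library accounted for most of that gap. Control libraries covered 121.5 ± 8.58 Mb and succinate libraries 107.8 ± 16.4 Mb (SD, n = 3 each), a difference of −13.7 Mb (exact permutation test, p = 0.3). The mean number of peaks was 111143 ± 10543 in controls and 96208 ± 9956 with succinate (exact permutation test, p = 0.3, n = 3 each). Succinate library 2 covered 89.0 Mb and held 2918 peaks with −log10 q of at least 5, against 6745 to 8631 in the other 5 libraries. Without it the difference in covered length was −4.36 Mb and that in number of peaks −9210. With 3 libraries per group no exact p can fall under 0.1.

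**Figure D1:**
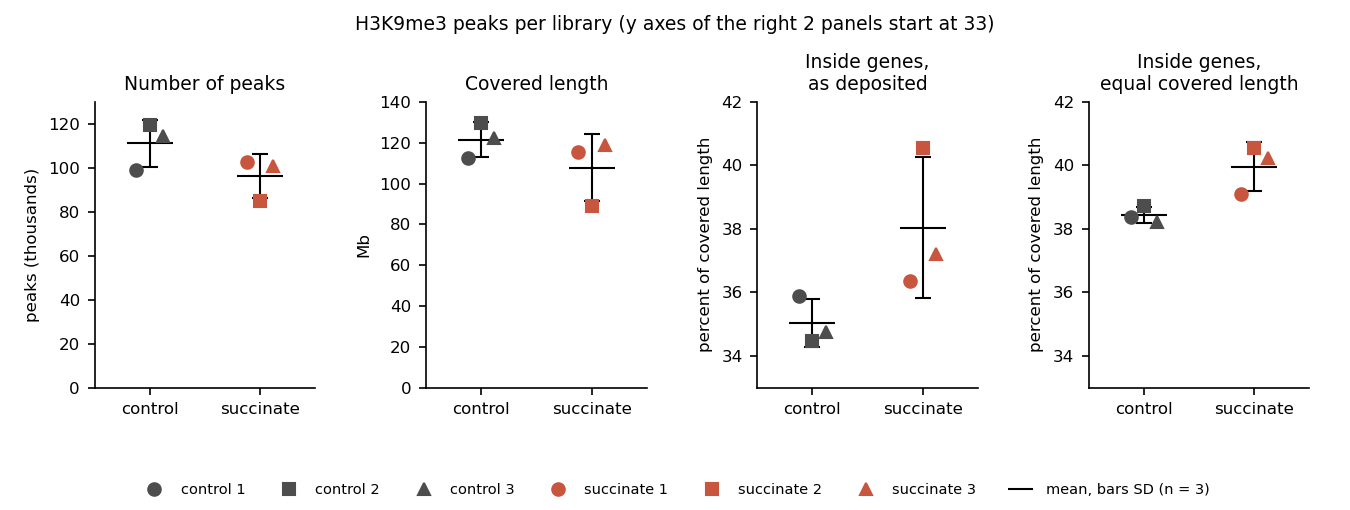
Number of peaks, covered length (Mb) and the percent of covered length inside protein-coding genes, as deposited and at equal covered length, for each library (points), with mean and SD (n = 3). Succinate library 2 has the shortest covered length, 89.0 Mb, and the share inside genes is higher in each succinate library than in any control in both right panels, whose axes start at 33%.

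The share of covered length inside genes was higher in each succinate library than in any control. Inside protein-coding genes lay 35.0% ± 0.745 of the covered length in controls and 38.0% ± 2.22 with succinate (SD, n = 3 each). The difference was 3.00 points (exact permutation test, p = 0.1, the smallest possible). With peaks of −log10 q of at least 5 the groups overlapped (exact permutation test, p = 0.2), with succinate library 2 at 65.3% and the other 5 at 49.4% to 50.8%. Gene bodies made up 41.6% of the chromosomes. The difference was 1.74 points without succinate library 2, and 1.52 points when all lists were cut to the same covered length (38.4% ± 0.265 and 39.97% ± 0.758, n = 3 each). Chromosome 19, where zinc finger genes are densest, was covered over 21.6% ± 0.613 in controls and 19.6% ± 2.56 with succinate. All 23 chromosomes had a lower mean with succinate, but 9 did at equal covered length and 10 after scaling by each library's covered percent. The smallest adjusted p over the chromosomes was 0.541 (exact permutation tests).

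Of the 10 genes with the largest lower coverage with succinate, 6 lay in a domain of imprinted and zinc finger genes on chromosome 19, and the other 4, like the 10 with the largest higher coverage, were single genes elsewhere. None passed the test: limma called 0 of 2071 genes, with 128 at an unadjusted p under 0.05 (73 higher and 55 lower with succinate), against 157 and 141 in 2 splits that mix the treatments. Among the tested genes 267 had groups that did not overlap, 12.9%, but 2 of the 9 splits that mix the treatments gave more, 314 (15.2%) and 320 (15.5%). In the domain, PEG3, an imprinted gene expressed from the paternal copy (chromosome 19, 56810082 to 56840726), was covered over 72.3% ± 5.39 in controls and 45.6% ± 23.8 with succinate. The other named genes of the domain had the same order, which the rule for named genes requires. ZIM2, whose stretch contains all of PEG3, was covered over 75.0% and 49.6%, and ZNF71 over 82.7% and 55.8%. SMIM17 was at 70.3% and 48.8%, ZIM3 at 71.8% and 48.7%, and ZNF264 at 76.0% and 51.8%. The values in succinate library 2 were the lowest in all 6 of these genes, 19.6% for PEG3 against 66.2% and 51.1% in the other succinate libraries. Without that library the differences went from −26.6 to −13.6 points for PEG3, −25.5 to −14.3 for ZIM2, −26.9 to −14.7 for ZNF71, −21.5 to −8.68 for SMIM17, −23.1 to −11.6 for ZIM3 and −24.3 to −10.6 for ZNF264. At equal covered length the groups still did not overlap for ZIM2, ZNF71, ZIM3 and ZNF264, whereas they overlapped for PEG3 and SMIM17. Not all of the domain was lower in every succinate library: in the 10-kb window at ZNF835 from 56660001 the groups overlapped. Controls 1 to 3 were there at 82.6%, 83.0% and 93.7%, and succinate libraries 1 to 3 at 91.1%, 26.3% and 82.65%.

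**Figure D2:**
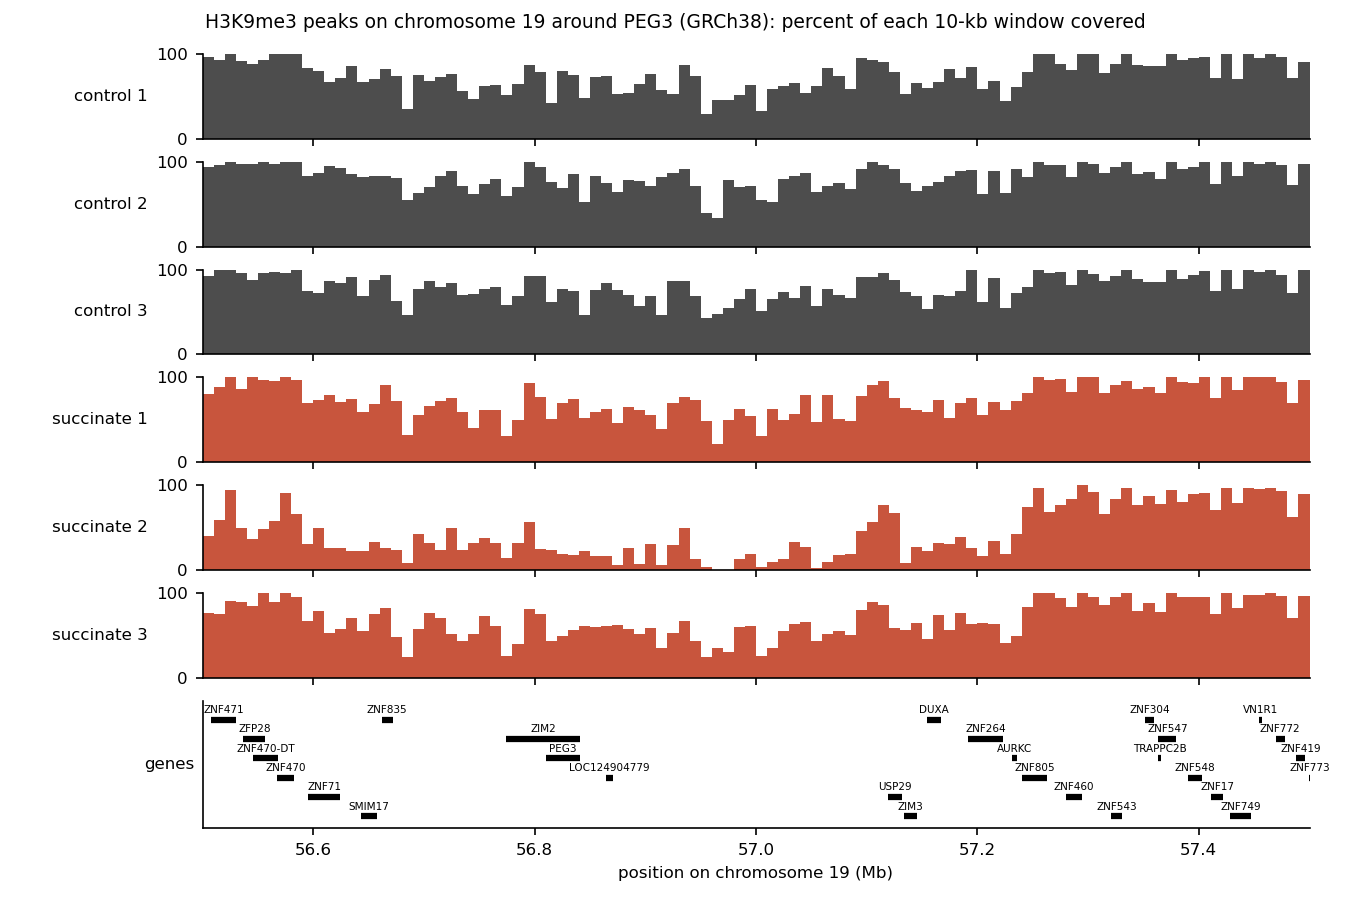
Percent of each 10-kb window covered by peaks on chromosome 19 from 56.5 to 57.5 Mb (GRCh38) in the 6 libraries (control grey, succinate red), with protein-coding genes as bars. Coverage from ZNF71 to ZNF264 is mostly lower in succinate library 2 (PEG3, 19.6%) than in the other libraries (51.1% to 77.7%), though not in the window at USP29 from 57120001 (67.0%, and 58.7% in succinate library 3), and closer among the 6 to the right of ZNF805.

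Other genes with lower coverage in each succinate library were AHSP, which encodes a chaperone of alpha-globin (60.7% ± 34.4 in controls, 0% in each succinate library), ZNF660 (73.8% and 49.4%), FPR3, a formyl peptide receptor (71.0% and 49.5%), and the predicted gene LOC124905938 (33.7% and 8.70%). Higher coverage in each succinate library was seen at FANCF, a member of the Fanconi anaemia core complex (chromosome 11, 22622533 to 22625823), with 3.19% ± 5.53 in controls and 23.4% ± 8.46 with succinate. The difference of 20.2 points had an SE of 5.04 (limma, adjusted p = 0.611). FANCF is 3.291 kb long and the median peak width was 541 to 598 bp, so its percent can turn on a few peaks. Control libraries 1 and 3 were at 0%. The other 9 were KBTBD7, a substrate adaptor of a ubiquitin ligase (7.63% and 24.2%), LOC124902928 (3.53% and 17.0%), RPL12, a ribosomal protein (49.8% and 62.4%), PSG9, a pregnancy-specific glycoprotein (7.78% and 19.1%), the RNA gene TUG1 (70.4% and 81.4%), MRPL50, a mitochondrial ribosomal protein (62.3% and 72.0%), SLC25A24, a mitochondrial carrier (20.7% and 27.1%), COX6C, a subunit of cytochrome c oxidase (15.8% and 21.8%), and CENPL, a centromere protein (7.08% and 12.8%). At equal covered length the groups did not overlap for 5 of the 10 higher genes (KBTBD7, RPL12, TUG1, MRPL50 and SLC25A24) and 5 of the 10 lower ones, whereas they overlapped for FANCF, where the difference of 20.2 points fell to 8.64. Those of PSG9, COX6C and CENPL fell there from 11.3, 6.00 and 5.73 points to 6.40, 2.19 and 2.00. With peaks of −log10 q of at least 5 the difference turned to −9.64 points for RPL12 and −0.151 for COX6C. For AHSP the difference of −60.7 points was −15.2 at equal covered length and the groups overlapped. Without succinate library 2 the differences of ZNF660 and FPR3 went from −24.3 and −21.4 points to −13.2 and −13.7. AHSP passed with nearby peaks joined (limma, adjusted p = 2.04e-05, and 2.04e-05 to 0.965 over all alternatives). The gene is 0.904 kb long, so its percent can turn on a single peak. With peaks joined its difference was −100 points, which leaves no spread within either group. LOC124905938 passed with −log10 q of at least 2 (limma, adjusted p = 0.00345, and 0.00345 to 0.965 over all alternatives). Scaled with array weights, PSG9 (limma, adjusted p = 0.0303) and SLC25A24 (0.0382) also passed, and over all alternatives their adjusted p ranged up to 0.965. The smallest adjusted p belonged to SIX6, a homeobox gene of eye development (chromosome 14, 60509146 to 60512850), named after its values were seen. It was covered over 10.2% ± 1.52 in controls and 0% in each succinate library (limma, difference −10.2, SE 0.805, adjusted p = 0.0656). Its adjusted p was 0.00766 after scaling by covered percent and 0.0262 on the arcsine scale. Over the 11 of 18 alternatives that tested the gene the value ranged from 0.00766 to 0.469. SIX6 met the filter of 5% mean coverage through the controls alone. It is a short gene, so its percent too can turn on a single peak. TMBIM4, also named afterwards, was covered over 10.5% ± 0.444 and 15.2% ± 0.231 (limma, adjusted p = 0.198; 0.0382 to 0.965 over all alternatives).

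**Figure D3:**
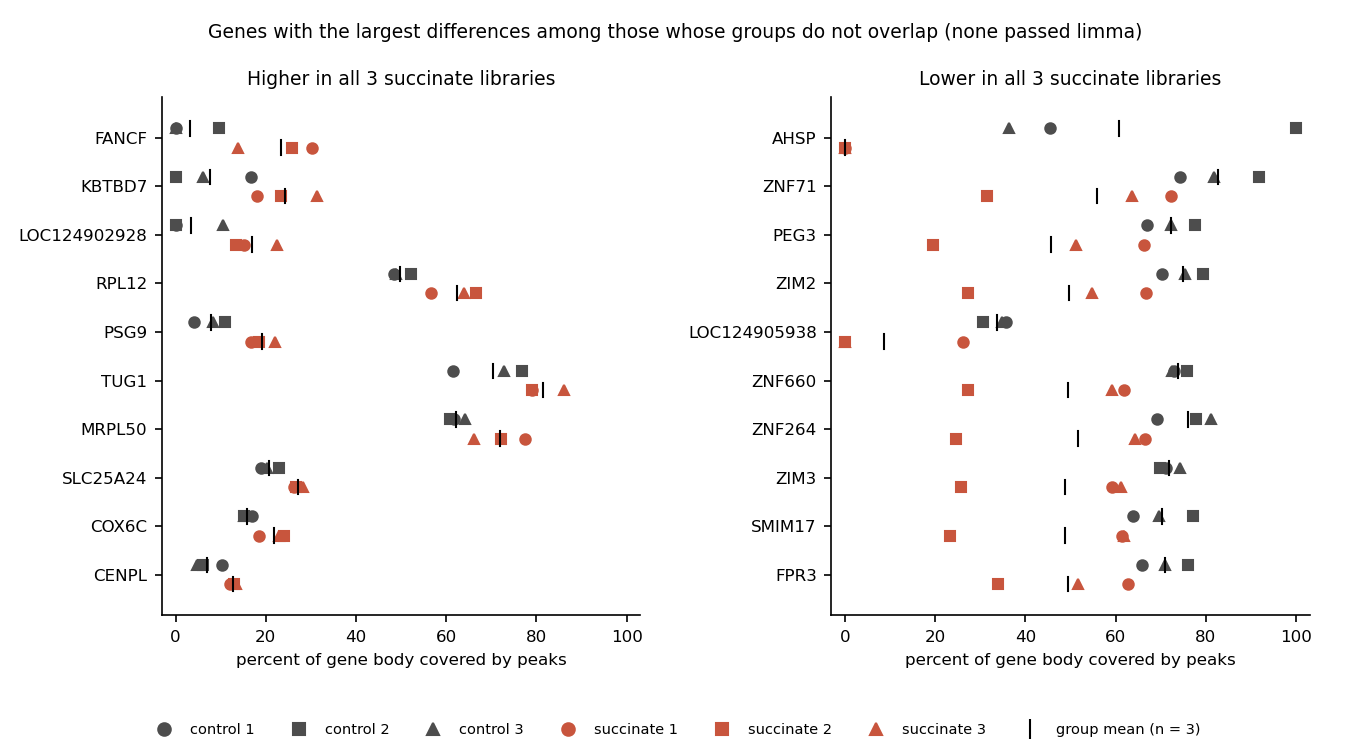
Percent of the gene body covered by peaks in each library (points; vertical ticks are group means, n = 3) for the 10 genes with the largest difference in each direction among genes whose groups do not overlap. AHSP is at 0% in all 3 succinate libraries, and in PEG3, ZIM2, ZNF71, ZIM3, SMIM17, ZNF264, ZNF660 and FPR3 succinate library 2 lies lowest.

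Windows of 10 kb gave no call either: limma called 0 of 32710, with 3428 at an unadjusted p under 0.05, 829 higher and 2599 lower with succinate, against 810 to 2393 in the 9 splits that mix the treatments. With peaks of −log10 q of at least 5, 14 windows were called higher and 50 lower. Among the largest differences without overlap was a window in MAPK14, which encodes the stress kinase p38 alpha (chromosome 6, 36080001 to 36090000, 26.8% in controls and 53.4% with succinate). Also higher were 1 near the breast-expressed MUCL1 (chromosome 12, 54870001 to 54880000, 19.5% and 45.8%) and 1 far from any protein-coding gene (chromosome 6, 92930001 to 92940000, 33.5% and 59.2%). Lower with succinate were a window near ZNF736 (chromosome 7, 64290001 to 64300000, 87.8% and 42.5%), 1 in the gene-poor stretch beside CYLC2 (chromosome 9, 102810001 to 102820000, 48.8% and 4.52%) and 1 near LOC124901643 (chromosome 7, 63850001 to 63860000, 91.8% ± 6.96 and 49.7% ± 26.1). In the last of these succinate library 2 was at 19.7%, and without it the difference of −42.1 points was −27.1. In the window near ZNF736 that library was at 18.75%, and without it the difference of −45.3 points was −33.4. The difference beside CYLC2 went only from −44.3 to −42.0 points. Adjusted p for these 6 windows lay between 0.311 and 0.394 (limma).

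Bases covered in every library of 1 treatment and none of the other added up to 2.29 Mb for controls and 1.02 Mb for succinate. At equal covered length they came to 1.24 Mb and 1.17 Mb, so the larger value for controls was nearly gone. In consensus regions, 83.4 Mb were shared, 28.4 Mb belonged to controls only and 17.4 Mb to succinate only. All 6 libraries had 49.2 Mb in common. The Jaccard index averaged 0.535 within treatments and 0.520 between them, and pairs with succinate library 2 had the lowest values, 0.448 to 0.496. The gap of 0.0149 shrank to 0.00306 without control library 2, 0.00331 without control library 3 and 0.00716 without succinate library 2, and grew to 0.0341 and 0.0307 without succinate library 1 or 3.

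Marks at gene ends were found in 1143 ± 60.4 genes in controls and 1098 ± 115 with succinate (SD, n = 3 each, exact permutation test, p = 0.7). The sign turned without succinate library 2 (19.3 more genes with succinate) and at equal covered length (62 more, p = 0.1, exact permutation test). Ends of 757 genes had a peak in all 6 libraries. In each succinate library and no control were 15 genes, among them the repair gene ERCC8, the drug-metabolising enzyme CYP3A5, the glycogen phosphorylase PYGL and TBC1D4, a regulator of glucose transport. In each control and no succinate library were 10, among them PDGFRA, the glutamate receptor gene GRIN3A, the pigmentation gene OCA2 and SIX6. The genes named here were chosen after the sets were seen.

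Among the 24 gene lists, zinc finger genes of chromosome 19, olfactory receptors and neuronal genes had lower coverage with succinate by camera with a preset correlation, and no list was called with an estimated one or by fry. The 246 zinc finger genes on chromosome 19 were covered over 81.1% ± 0.803 in controls and 78.0% ± 4.19 with succinate (SD, n = 3 each), and the difference of −3.08 points turned to 7.17 after scaling by each library's covered percent. The camera adjusted p was 8.88e-06, with adjusted p = 0.665 with an estimated correlation. Of its 221 tested members, 32 were lower and 4 higher in every succinate library. Members are not independent, and this count was not set against mixed splits. Succinate library 2 lay at 73.1%, and the other 2 succinate libraries at 80.3% and 80.5%, within the control range of 80.2% to 81.7%. Without succinate library 2 the difference was −0.661 points (camera adjusted p = 0.00462; adjusted p = 0.768 with an estimated correlation). Olfactory receptors, the odorant-sensing receptors of the nasal epithelium, were covered over 1.82% ± 0.288 and 1.20% ± 0.379, lower in each succinate library than in any control (camera adjusted p = 0.000651; adjusted p = 0.631 with an estimated correlation). Their difference of −0.621 points was −0.240 at equal covered length, where the groups overlapped (exact permutation test, p = 0.2). OR1L4 was covered over 100% in the controls and 57.4% ± 44.8 with succinate (a difference of −42.6 points, and −19.3 without succinate library 2), and OR4C12 over 30.8% ± 26.9 and 0%. Control library 3 was at 0% for OR4C12, which limma called only when that library was left out (adjusted p = 0.0307; 0.0307 to 0.935 over all alternatives), and at equal covered length its difference was 0. Neuronal genes were covered over 2.24% ± 0.289 and 1.79% ± 0.356 (camera adjusted p = 0.0034; adjusted p = 0.631 with an estimated correlation), and their difference of −0.448 points was −0.0662 at equal covered length. The potassium channel gene KCNQ3 was at 6.18% and 3.76% (−2.42 points, and −1.33 at equal covered length, where the groups overlapped), the synaptic gene LRRTM4 at 3.67% and 1.58% (a difference of −2.09 points, and −0.468 at equal covered length), and the adhesion gene DSCAM, going the other way, at 6.20% and 7.47%. With stricter peaks (−log10 q of at least 5) olfactory receptors and neuronal genes were no longer called by camera (adjusted p = 0.980 and 0.766), and with nearby peaks joined the zinc finger genes of chromosome 19 were not (adjusted p = 0.0515).

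**Figure D4:**
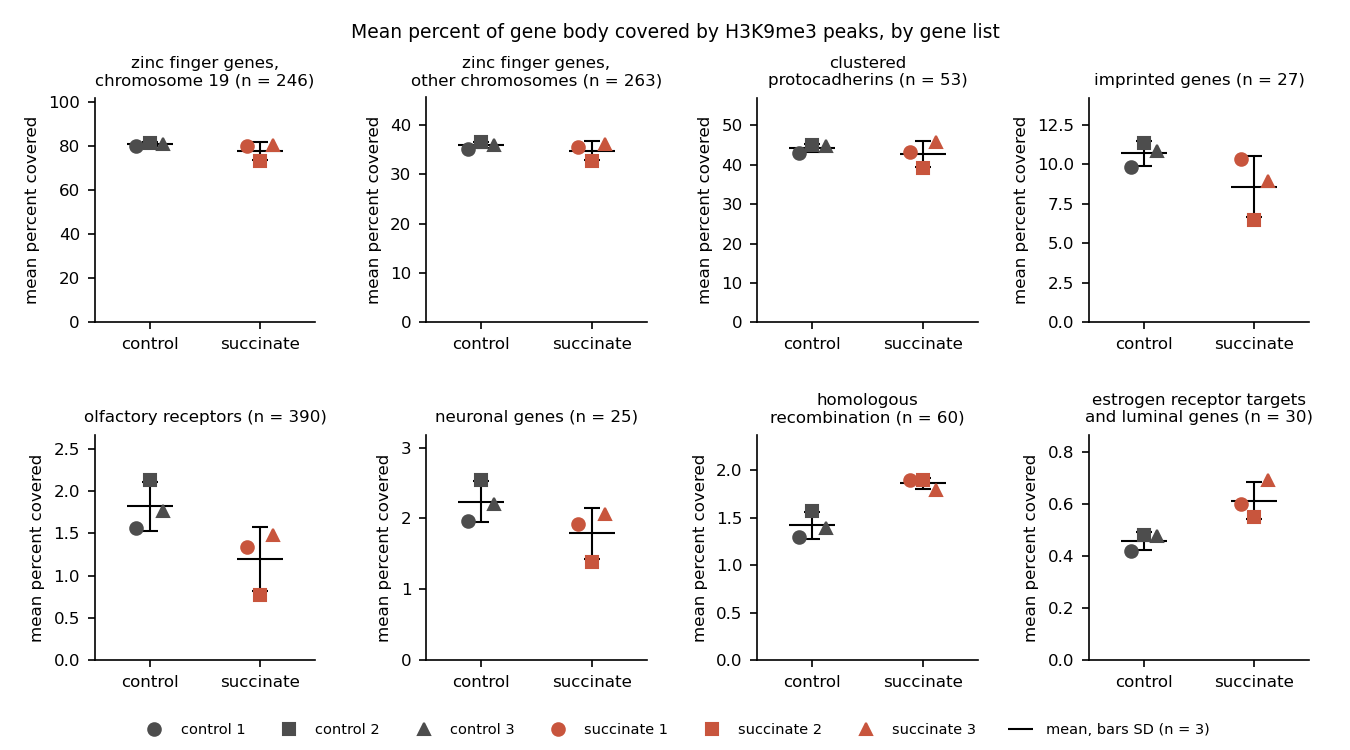
Mean percent of gene body covered by peaks over the members of 8 gene lists in each library (points), with mean and SD (n = 3). Homologous recombination genes lie at 1.80% to 1.90% in the succinate libraries and at 1.30% to 1.58% in controls, and succinate library 2 is lowest for zinc finger genes, protocadherins, imprinted genes, olfactory receptors and neuronal genes.

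Homologous recombination genes, the repair pathway named in the series title, were not called as a list by any test of the main analysis. Their mean coverage was 1.42% ± 0.141 in controls and 1.86% ± 0.0591 with succinate (SD, n = 3 each), higher in each succinate library (exact permutation test, p = 0.1, the smallest possible; adjusted over the lists 0.48). Camera gave an adjusted p = 0.0938, and adjusted p = 0.631 with an estimated correlation (0.046 and 0.763 without succinate library 1). FANCF carried most of it: without that gene the difference of 0.442 points was 0.107 and the groups overlapped. They also overlapped at equal covered length (0.307 points, exact permutation test, p = 0.2) and with −log10 q of at least 5 (0.0378 points, p = 0.8). Of 7 tested members FANCF alone had groups apart, and 0 passed limma when adjusted over the list alone (smallest adjusted p = 0.0613). BRIP1, a helicase that binds BRCA1, had the highest coverage in the list (22.7% ± 0.161 and 24.0% ± 2.45). BRCA1, BRCA2 and ATM, which are breast cancer susceptibility genes, were covered over less than 1% in every library, with means of 0.558% and 0.347%, 0.673% and 0.452%, and 0.208% and 0.555%. The differences of BRCA1 and BRCA2 turned from −0.211 and −0.221 points to 0.347 and 0.342 at equal covered length, and that of ATM shrank from 0.347 to 0.0116. With −log10 q of at least 2 all 3 turned, to 0.347, 0.239 and −0.0694. RAD51 and PALB2 had no covered base in any library.

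None of the lists of other repair genes, H3K9 enzymes and succinate metabolism was called in the main analysis. End-joining genes were covered over 1.41% ± 0.136 and 1.56% ± 0.117, with the nuclease gene DCLRE1C at 12.2% and 14.7% (2.43 points, and 1.253 at equal covered length) and XRCC4 at 8.21% and 9.17%. PARP and single-strand break repair genes were at 0.407% and 0.331%, lower in each succinate library (exact permutation test, p = 0.1, n = 3 each; adjusted over the lists 0.48). The 2 covered members were TDP1 (3.74% and 2.76%) and PARG (1.14% and 1.20%), and without TDP1 the groups overlapped. With −log10 q of at least 5 the difference of TDP1 turned from −0.974 to 0.729. H3K9 methyltransferases and their partners were at 3.49% and 3.60%. Of these, SETDB1 was at 3.72% and 3.80%, and its partner ATF7IP at 34.6% ± 2.24 and 35.2% ± 2.01. The difference of SETDB1, 0.0771 points, was 1.42 with −log10 q of at least 5. With a library left out it ran from −0.0554 to 0.281. The 2-oxoglutarate-dependent dioxygenases were at 1.67% ± 0.136 and 1.86% ± 0.140 (camera adjusted p = 0.0621; adjusted p = 0.631 with an estimated correlation), with PHF2 at 11.9% and 12.6% and KDM5A at 6.35% and 7.83%. The H3K9 demethylase KDM4A had no covered base, KDM4B was at 1.48% and 1.37% (a difference of −0.107 points that turned to 0.0497 at equal covered length) and KDM4C at 0.836% and 1.03%, where the difference of 0.194 turned to −0.134 with −log10 q of at least 2 and −0.300 with at least 5. Genes of the tricarboxylic acid cycle and succinate transport were at 1.08% and 1.21%. In that list SUCLA2, a subunit of succinyl-CoA synthetase, was at 16.2% and 16.6%, and SUCNR1, the succinate receptor, at 1.02% ± 1.77 and 3.82% ± 1.31. Targets of hypoxia-inducible factor were at 0.728% and 0.737%, with PDK1 at 9.24% and 9.63%.

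Of the genes that define the cells, estrogen receptor targets and luminal genes were covered over 0.459% ± 0.0356 in controls and 0.613% ± 0.0727 with succinate, higher in each succinate library (exact permutation test, p = 0.1, n = 3 each; camera adjusted p = 0.0574; adjusted p = 0.631 with an estimated correlation). PGR, the progesterone receptor gene (chromosome 11, 101029624 to 101129813), was at 3.58% ± 0.505 and 6.46% ± 1.24. Its difference of 2.89 points was 4.77 at equal covered length. With limma its adjusted p was 0.611 over all genes and 0.0179 adjusted over the list alone, which has 2 tested members. Over all genes it was 0.0303 to 0.965 in the 11 of 18 alternatives that tested PGR, the lowest when scaled with array weights. The control mean lay under the filter of 5%, so PGR was tested only through its higher succinate values. Without succinate library 2 it did not meet the filter. Without PGR the list's difference of 0.155 points was 0.0605 and the groups overlapped, as they did with −log10 q of at least 5 (0.000836 points, exact permutation test, p = 0.8). ESR1, the estrogen receptor gene, was at 5.20% ± 0.846 and 5.85% ± 0.579. Its groups overlapped with a difference of 0.644 points, whereas at equal covered length the difference was 1.22 and they did not. Over all alternatives that tested ESR1 the adjusted p was at least 0.165 (limma). Among markers of other cell types, basal and mesenchymal genes were at 0.962% and 0.953%, with ZEB1 at 4.56% and 5.12% (a difference of 0.567 that turned to −0.293 with −log10 q of at least 5), and blood cell genes at 1.03% and 1.11%, where the median difference of the covered members was −0.105 and CD14 alone made the mean positive, through succinate library 3. Cell cycle genes were at 0.0561% and 0.128%, higher in each succinate library (exact permutation test, p = 0.1, n = 3 each), with GINS1 at 0.407% and 1.57%. Without GINS1 their groups overlapped, as they did at equal covered length (a difference of 0.0720 points, and 0.0432 at equal length, exact permutation test, p = 0.4). Interferon and viral sensor genes were at 1.79% and 1.72%, with OAS2 at 11.4% and 12.8% and DDX60 at 4.60% and 3.52%.

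Among gene families that lie in clusters, zinc finger genes outside chromosome 19 were covered over 35.8% ± 0.617 and 34.7% ± 1.89. Their difference of −1.11 points was −0.0255 without succinate library 2 and turned to 3.45 after scaling by covered percent. In that list ZNF479 was at 66.6% and 45.7%. For ZNF479 the groups overlapped, and its difference of −20.9 points was −8.97 without succinate library 2 and −9.53 at equal covered length. Clustered protocadherins were at 44.2% ± 1.03 and 42.6% ± 3.33, where scaling turned the difference to 3.95 points and leaving out succinate library 2 to 0.248. In that list PCDHB3 was at 43.2% and 28.8%, with groups that overlapped. Its difference of −14.5 points ran from −21.7 to −8.37 with a library left out. Imprinted genes were at 10.7% ± 0.781 and 8.60% ± 1.94, mostly through PEG3 and ZIM2, with a difference of −2.10 points and −1.05 without succinate library 2. Cancer-testis families of the X chromosome were at 0.641% and 0.510%, with PAGE2B at 6.31% and 2.52% (−3.79 points, and −1.50 at equal covered length, where the groups overlapped) and MAGEC1, going the other way, at 18.9% and 21.9%. The difference of these families turned to 0.0275 at equal covered length. Keratin-associated proteins were at 2.32% and 1.93%, a difference of −0.391 points that was −0.132 without succinate library 2. Beta-defensins, antimicrobial peptides, were at 0.384% and 0.270%, with a positive median of 0.990 over 3 covered members. In that list DEFB125 (chromosome 20, 87672 to 97094) was at 14.9% ± 2.76 and 6.06% ± 0.480 (limma, adjusted p = 0.438 over all genes and 0.00127 adjusted over the list alone, of 1 tested member). Ribosomal protein genes were at 1.16% and 1.09%. Without RPL10L, which was at 71.4% in control library 3, the list's difference turned from −0.0622 to 0.132 points, higher in each succinate library. In that list RPL12 passed adjusted over the list alone (limma, adjusted p = 0.0371, 3 tested members). Replication-dependent histone genes had coverage in H4C13 only (listed at 0% in controls, 46.2% ± 39.98 with succinate). Succinate library 3 was at 0% for H4C13, so the call when it was left out (limma, adjusted p = 0.00115; 0.00115 to 0.965 over all alternatives) follows from that choice. Glucuronosyltransferases and cytochrome P450 genes were at 2.13% and 2.11%, with a median difference of 0.0707 and CYP2C18 at 6.51% and 4.10%.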

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

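Array weights, scaling with array weights and windows of 100 kb were chosen after seeing the data. In the planned and added alternatives run on them, the lower number of peaks, the shorter covered length, the higher share inside genes and the higher similarity within treatments kept their direction and, where tested, their side of the threshold. With 3 libraries per group the exact tests cannot pass 0.05, so they say nothing of stability. The labels do not state whether libraries of the same replicate number share a day. Same-number correlations of deviations were −0.145, −0.113 and 0.0151 over windows and −0.107, −0.0678 and 0.169 over genes. Not every library correlated best with its own number, but with 3 libraries per group these correlations cannot exclude a pairing. With the replicate block limma called 0 genes and 0 windows, camera called 4 lists lower, and covered length differed by −13.7 Mb (exact sign-flip test, p = 0.5, smallest possible 0.25). Unless said otherwise the cause of a change below was not tested.

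Scaling with array weights gave 33 genes higher and 5 lower, and 125 windows higher and 257 lower. Genes called lower numbered 1 with −log10 q of at least 2, with peaks joined, on the arcsine scale, scaled and without the filter, and 2 with −log10 q of at least 5. Windows called were 14 higher and 50 lower with −log10 q of at least 5, and called lower were 2 with peaks joined, 1 on the arcsine scale and 4 in windows of 100 kb at equal covered length. Leaving out libraries gave 0 to 1 genes higher and 0 to 1 lower. Camera called 1 list higher with −log10 q of at least 2 and 2 when scaled (0 to 1 with a library left out), and 5 lower with −log10 q of at least 2 and 6 at equal covered length. With an estimated correlation it called 0 in every alternative. Fry called 2 lists when scaled (estrogen receptor targets and luminal genes, and the tricarboxylic acid cycle) and histones without succinate library 3. The higher lists were estrogen receptor targets and luminal genes (−log10 q of at least 2, scaled, without control library 3), zinc finger genes of chromosome 19 (scaled), homologous recombination (without succinate library 1) and histones (without succinate library 3). Beyond the 3 lists of the main analysis, protocadherins and beta-defensins were lower with −log10 q of at least 2 and at equal covered length, and zinc finger genes outside chromosome 19 at equal covered length. Protocadherins were also lower with −log10 q of at least 5, on the arcsine scale and without succinate library 3, and cancer-testis families with the replicate block and when scaled.

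Bases in every control and no succinate library came to 0.569 Mb with −log10 q of at least 5 and 1.24 Mb at equal covered length. Those in every succinate and no control library came to 0.132 Mb with −log10 q of at least 5 and 1.17 Mb at equal covered length. With fewer libraries to agree they were 3.03 to 6.40 Mb and 1.87 to 3.52 Mb. Consensus bases of succinate only were 10.8 Mb when all 3 libraries had to agree. Chromosomes lower in mean were 9 at equal covered length and 10 when scaled. Gene ends with a peak differed by 62 at equal covered length, and by −90.7 to 19.3 with a library left out. Gene ends in controls only were 5 with −log10 q of at least 5, 6 at equal covered length, 3 where 50% of the 2 kb had to be covered and 12 to 29 with a library left out. In succinate only they were 8 with −log10 q of at least 2, 1 with at least 5, 3 with 50% covered and 19 to 32 with a library left out.

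Mean list differences turned sign in 14 of the 24 lists in at least 1 alternative, and in 12 if scaling is left out. With −log10 q of at least 5 they were −0.0736 for dioxygenases, −0.185 for H3K9 methyltransferases, 0.137 for PARP genes, −0.333 for blood cell genes and −0.00635 for end joining. With at least 2 they were 0.0761 for cytochrome P450, 0.0495 for cancer-testis families and 0.0808 for ribosomal proteins. At equal covered length they were 0.247 for cytochrome P450, 0.0250 for basal genes, 0.0275 for cancer-testis families, 0.0273 for interferon genes and 0.170 for ribosomal proteins. Scaled, they were 0.219 for cytochrome P450, 0.107 for basal genes, 3.95 for protocadherins, 0.130 for interferon genes, 0.0860 for ribosomal proteins, 7.17 for zinc finger genes of chromosome 19 and 3.45 for the others; genes near 100% covered gain from scaling by construction. With a library left out they ran from −0.187 to 0.276 for cytochrome P450, −0.0797 to 0.0651 for basal genes, −0.216 to 0.303 for blood cell genes, −3.04 to 0.248 for protocadherins, −0.0299 to 0.0366 for hypoxia targets, −0.168 to 0.131 for interferon genes and −0.233 to 0.239 for ribosomal proteins. Beta-defensins, cell cycle genes and histones had no coverage with −log10 q of at least 5.

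Among named genes with a test, 8 turned sign in at least 1 alternative, and 7 if scaling is left out, since ZNF154, covered over 100% in controls, turned only there. With −log10 q of at least 5 the differences were −1.97 for ATF7IP, −0.151 for COX6C, −2.18 for PHF2, −9.64 for RPL12 and −0.0489 for SUCLA2. With array weights ATF7IP was at −0.704. ZNF154 was at 12.3 when scaled and 4.49 scaled with array weights. With a library left out the differences ran from −0.301 to 1.88 for ATF7IP, −0.0749 to 2.16 for BRIP1, −0.152 to 1.09 for PDK1, −0.134 to 1.56 for PHF2 and −0.263 to 1.53 for SUCLA2. Depth, which limits weak peaks, is unknown.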

Other observations

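The tests of 500-kb regions, of covered length, of all splits of the libraries, and of the share inside genes at equal covered length or without succinate library 2 were chosen after the values were seen, as were the regions and genes named in this part. The test outside zinc finger genes and the correlations across windows were set before their results.

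Some regions of 500 kb had a covered percent higher or lower in every succinate library than in any control. Within such a region single 10-kb windows could still overlap between the groups, as did that from 226170001 on chromosome 2. At equal covered length 85 of 208 regions with at least 10% mean coverage had groups that did not overlap, 40 higher and 45 lower with succinate, against at most 27 in a split that mixes the treatments. With the lists as deposited it was 89 of 315, 21 higher and 68 lower, against up to 72 in a mixed split. Higher with succinate was a stretch of chromosome 2 without protein-coding genes (226000001 to 226500000), between NYAP2 and IRS1, the insulin receptor substrate gene. It was at 31.3% ± 2.77 in controls and 38.7% ± 2.98 with succinate (SD, n = 3). A stretch of chromosome 10 (8500001 to 9000000), also without protein-coding genes, was at 17.2% ± 0.335 and 21.9% ± 2.48. Such a stretch of chromosome 12 (97500001 to 98000000) was at 15.9% ± 0.809 and 20.4% ± 3.26. These 3 were picked for having every succinate library above all controls, so the place of succinate library 2 there follows from the choice. Lower with succinate were 3 adjoining regions of chromosome 17 (53500001 to 55000000) that hold KIF2B, TOM1L1, COX11 and STXBP4, with 15.8%, 21.1% and 17.3% in controls and 8.31%, 11.3% and 9.82% with succinate. A region around DCAF4L2 on chromosome 8 (87500001 to 88000000) was at 21.9% ± 2.33 and 11.1% ± 5.59. The region of ZNF471 to PEG3 on chromosome 19 (56500001 to 57000000) was at 75.8% ± 4.56 and 53.2% ± 19.9. The groups of the regions named here did not overlap at equal covered length either. The lower differences on chromosome 17 shrank there from −7.52, −9.75 and −7.45 points to −3.99, −4.93 and −2.75, and that around DCAF4L2 from −10.9 to −5.05. The region of chromosome 19 went from −22.6 to −20.7, and that of chromosome 2 from 7.39 to 10.8. In the region of chromosome 19 succinate library 2 was at 30.5%, against 67.4% and 61.6% in succinate libraries 1 and 3, so much of that difference rests on it.

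Some genes whose symbols do not mark them as zinc fingers or protocadherins were covered over at least 90% in every library. They included UBE3A, the ubiquitin ligase gene of Angelman syndrome (chromosome 15, 25333728 to 25439056), and the kinase gene MAPK9 on chromosome 5. KRABD5 on chromosome 16 and PPP2R1A, a scaffold subunit of protein phosphatase 2A, on chromosome 19 (52190052 to 52229518) were others. UBE3A was covered over 95.4% to 97.6% in the 6 libraries.

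A larger share of the mark inside genes was the first pattern weighed. Unequal covered length as the whole cause is argued against by a difference of 1.52 points at equal covered length, with every succinate library above every control. Outside zinc finger genes and chromosome 19, at equal covered length, it was 1.92 points (33.4% ± 0.251 and 35.3% ± 0.984), so strong zinc finger peaks kept by a weaker library do not account for it. Without succinate library 2 it was 1.74 points, above the control SD of 0.745 (exact permutation test, p = 0.2). With peaks of −log10 q of at least 5, however, the other 2 succinate libraries overlapped the controls. A candidate explanation that stays open is a change with succinate in how the mark is divided between genes and intergenic regions. It cannot be told apart from an effect of the separate inputs of the treatments. As deposited, the covered length was lower with succinate (107.8 Mb, and 121.5 Mb in controls). A larger share inside genes can therefore come from less covered length outside them, and does not show a gain inside genes. Chance stays open too, since no exact p can fall under 0.1 with 3 libraries per group. The share also rose with peak strength, in controls from 35.0% to 49.99% with −log10 q of at least 5. A dependence on library strength beyond zinc finger genes was not tested.

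The second pattern was the shorter covered length with succinate. Without succinate library 2 the difference was −4.36 Mb, smaller than the control SD of 8.58 Mb, which is consistent with 1 weaker library as its source. Why that library was weaker was not tested.

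The third was that differences across 100-kb windows pointed the same way in independent pairs of libraries. The difference between succinate library 2 and a single control was correlated with that between the other succinate and the other control libraries, with the lowest of 3 correlations at 0.658 (across 2344 windows, which are not independent replicates), and at 0.352 with any succinate library in its place. At equal covered length these were 0.661 and 0.381. Regroupings that mix the treatments reached 0.682 with the lists as deposited and 0.644 at equal covered length, so the bound of 0.1 set beforehand was too low to show that the agreement follows the treatment. Unequal covered length and a departure of succinate library 2 for a reason of its own both stay open.

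The 6 libraries can be split in 10 ways, so no share of splits can fall under 0.05, and only the real value and the highest of the other splits are given. For genes, limma called 0 in the real split and at most 1 in another, so that all 10 splits gave at least as many. For windows the number was 0 in all 10. Camera called 3 lists in the real split and at most 2 in another, and 1 of the 10 splits (the real one) gave as many, whereas with an estimated correlation camera called 0 in all 10, as fry did. The length covered in every library of 1 group and none of the other was 3.31 Mb against at most 2.67 Mb (1 of 10 splits as large). Similarity within groups exceeded that between groups by 0.0149 against at most 0.00673 (1 of 10). Gene ends with a peak in every library of 1 group and none of the other numbered 25 against at most 16 (1 of 10). Regions of 500 kb with groups apart at equal covered length numbered 85 against at most 27 (1 of 10).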
